A study of Arabidopsis thaliana with 8 samples.

How the data were processed

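Floral stem tissue of Arabidopsis thaliana accession Col-0 was profiled by mRNA sequencing. Per the labels, the plants were wild type (WT) or msh1 and grew under long days, and each genotype gave a Total sample and a TRAP sample. TRAP, translating ribosome affinity purification, pulls down ribosomes that carry an epitope-tagged ribosomal protein together with the mRNAs they hold. Here the tagged protein was FLAG::RPL18 under the MSH1 promoter. TRAP libraries are thus meant to hold RNA on ribosomes of cells that use this promoter, and Total libraries RNA of the stem as a whole. MSH1 encodes a DNA mismatch repair protein homologue of plastids and mitochondria. The 8 libraries form 4 groups of 2, WT Total, WT TRAP, msh1 Total and msh1 TRAP, each taken from the sample title. The labels call the replicates biological and do not say whether Total and TRAP samples came from the same plants, so the main fit used no pairing. Each p-value rests on the spread between 2 libraries per group, pooled over all 4 groups.

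Per the labels' protocols, RNA was extracted with a plant RNA column kit, libraries were made with the TruSeq RNA v2 preparation and sequenced as paired-end reads on a HiSeq 4000. The authors deposited 1 table of raw read counts per library, with whole numbers per locus and no normalization. The submitters' processing notes name the TAIR10 genome build and DESeq2, and the aligner and the counter are not given in the sources used here. The preparation named does not mark strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. In the annotation, 2596 loci overlap another locus over at least 0.5 of the shorter one's exons, where that locus holds at least 0.2 times as many counts, and named genes of this kind are called uncertain. Each table ends with 5 lines that name no gene, which stayed out of library sizes and tests. Reads assigned to no gene made up 38.5 to 41.68% of all listed counts. Whether the counting used strand is not given, so reads on the opposite strand of a gene may be among them. Reads without a unique alignment made up 12.35 to 18.95%, and ambiguous reads 0.16 to 0.31% in TRAP and 0.58 to 1.12% in Total. Genes with near-identical copies therefore lost reads, and values of gene families such as LHCB1, LHCB2 or the PDF1.2 defensins are uncertain between members.

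Gene counts summed to between 7568728 and 13611280 per library, and 3 counts, taken as the floor, stand for 0.22 to 0.396 CPM, the count scaled to a common library size. Intervals and floors of this kind cover counting error only. The tables list 32833 loci, of which 32548 matched the TAIR10.1 annotation by locus identifier, and every locus left over was an organelle locus. The 133 plastid and 152 mitochondrial loci held 0 counts in all 8 libraries, so organelle transcripts were not measurable, and scaling without organelle genes moves nothing and was not run. Transposable element genes were not tested as a list, because the annotation used does not give them as a gene class. Symbols and coordinates come from the TAIR10.1 annotation, and a locus without a symbol of its own is named by its identifier.

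Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 21202 genes, library sizes were scaled by the TMM method, and a quasi-likelihood F test was run in 1 fit of all 8 libraries and 4 groups, leaving 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold. The 5 contrasts were TRAP against Total in each genotype, msh1 against WT in each fraction, and the genotype by fraction interaction, which is the msh1 effect in TRAP minus that in Total. Log2 fold changes are given with their standard error (SE), levels as TMM-normalised CPM with mean ± SD and n = 2. Fold changes of the 2 TRAP contrasts, and of the 2 genotype contrasts, were compared across genes with Pearson's r and Spearman's rho. The libraries were also compared by principal components of log2 CPM with a prior count of 2.

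Gene lists were fixed before the data were examined, as were the samples, contrasts, tests and most of the other settings tried. The 20 lists written by locus covered nuclear photosynthesis genes, epidermis and cuticle, stomatal lineage and guard cells, phloem, cambium with xylem and secondary wall, lignin biosynthesis, floral organs, circadian clock, heat shock, mitochondrial dysfunction response, salicylic acid and defence, jasmonate, abscisic acid with drought and cold, auxin, cell division, DNA methylation and RNA-directed DNA methylation (RdDM), organelle DNA maintenance, touch and wound early response, flavonoid and anthocyanin, and glucosinolate. Lists from the annotation were cytosolic ribosomal proteins, of which the product wording found 20, and non-coding RNA genes. The ribosomal list holds only loci that this wording matched and does not stand for the whole family. Non-coding loci that overlap another locus were kept, so their counts may hold reads of that locus in every comparison. A6 and SSB1 were left out because the annotation names their loci otherwise, and AOP2 because its locus is not in the tables used here. The 22 lists were tested against all other genes with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and again with the correlation estimated from the data, and adjusted over the lists within each contrast. No camera call at the preset value held with an estimated correlation in any contrast. A list of 30 seed markers and the snoRNA and snRNA genes of the annotation were added after values had been seen and are described by counts, without camera.

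MSH1 and RPL18 (AT3G05590) were named in every comparison. Other genes were named by a rule: among genes past the threshold with a mean of at least 5 CPM, a symbol and both libraries of one group above both of the other, the 8 largest changes in each direction, and up to 3 members per list with the largest changes past the threshold. The clause on libraries has no meaning for the interaction and was not applied there. Of the genes this rule gave, the text names mainly those whose call held under every alternative, a narrowing made after the values were seen, and for others it gives the setting that ended the call. Genes marked as chosen after their values were seen lie outside the rule.

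Alternatives were DESeq2 1.42.0, edgeR with RLE or upper-quartile factors, limma-voom, no filter on low counts, at least 5 CPM in 2 libraries, the replicate number as an added term, only the 4 libraries compared, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. Added after seeing the data were fits in which a per-library lowess trend (span 0.3) of log2 CPM on transcript length, or on transcript GC content, was removed as an offset. Protein motifs were searched in the annotated proteins of 27444 nuclear genes, and a motif set was set against 10000 random sets matched on expression in 20 bins, with 100000 permutations for rank correlations across genes (SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3).

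The tests were checked on simulated counts drawn from the real means and library sizes, with known changes in about 100 genes at 2-fold and 100 at 4-fold. With 20867 genes, WT TRAP vs WT Total recovered 61.6% of 2-fold and 89.8% of 4-fold changes, with 9 false calls. With 20851 genes, msh1 TRAP vs msh1 Total recovered 56% and 90.7%, with 12 false calls. With 20850 genes, msh1 Total vs WT Total recovered 65.3% and 97%, with 20 false calls. With 20863 genes, msh1 TRAP vs WT TRAP recovered 59% and 92.6%, with 18 false calls. For the genotype by fraction interaction, with 20867 genes, 19.2% and 84.4% were recovered, with 12 false calls. In each contrast camera called the 1 changed list and 0 of 20 unchanged lists over 21202 genes. The simulated genes varied independently and the lists were random, whereas correlations estimated in the real lists reached 0.81. The simulation therefore cannot show false calls that come from correlation between genes. Each simulated gene also had the same spread in all 4 groups. In the real data chi-square per gene between replicates was 17.58 in msh1 TRAP and 5.21 in msh1 Total. Recovery and false calls in the real data may therefore differ from the simulated ones. A simulated length trend between msh1 TRAP and WT TRAP over 20946 genes gave 3049 calls, and 2 after the trend was removed.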

Results

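The data were read counts per gene from mRNA sequencing of Arabidopsis floral stems, in 8 libraries. They formed 4 groups of 2 biological replicates, WT Total, WT TRAP, msh1 Total and msh1 TRAP. Total libraries held RNA of the stem as a whole, and TRAP libraries held RNA purified with ribosomes that carried FLAG::RPL18 made under the MSH1 promoter. Gene counts summed to 11638497 and 13611280 in WT Total, 7568728 and 10816397 in WT TRAP, 10067810 and 11930121 in msh1 Total, and 7978556 and 9712422 in msh1 TRAP. The 10 most abundant genes held 6.73 to 9.77% of the counts of a library.

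The MSH1 transcript (AT3G24320, chromosome 3, 8822924 to 8829728, minus strand, TAIR10.1 annotation) was present in every library and higher in the libraries labelled msh1. It stood at 9.27 and 9.61 CPM in WT Total, 12.3 and 14.0 CPM in WT TRAP, 27.9 and 30.8 CPM in msh1 Total, and 36.3 and 22.5 CPM in msh1 TRAP. The msh1-labelled libraries exceeded WT by a log2 fold change of 1.63 ± 0.22 in Total (SE, edgeR adjusted p = 0.000972). In TRAP they exceeded it 2.22-fold, by 1.15 ± 0.22 (edgeR adjusted p = 0.00135). TRAP and Total did not differ detectably for MSH1 in WT, at 0.48 ± 0.23 (edgeR adjusted p = 0.259), or in msh1, at 0.00 ± 0.20 (edgeR adjusted p = 1), and the interaction was −0.48 ± 0.31 (edgeR adjusted p = 0.31). The allele is not stated in the sources used here, so the transcript level does not test the genotype, and every direction below is between libraries as labelled.

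RPL18 (AT3G05590, chromosome 3, 1621355 to 1623052, plus strand), the gene whose coding sequence the TRAP construct carries, was highest in msh1 TRAP. Its level was 283 ± 14.4 CPM in WT Total, 274 ± 6.04 CPM in WT TRAP, 336 ± 11.2 CPM in msh1 Total and 1360 ± 716 CPM in msh1 TRAP (SD, n = 2 each), where the libraries stood at 849 and 1860 CPM. In msh1, TRAP exceeded Total by a log2 fold change of 2.01 ± 0.28 (edgeR adjusted p = 0.000589), and in WT the difference was −0.05 ± 0.27 (edgeR adjusted p = 0.946). Between genotypes the difference was 2.31 ± 0.28 in TRAP (edgeR adjusted p = 9.5e-05) and 0.25 ± 0.27 in Total (edgeR adjusted p = 0.728). Reads of the transgene cannot be told from those of the endogenous gene in a table of counts per gene.

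The comparison of WT TRAP with WT Total asks which transcripts sit on tagged ribosomes of cells that use the MSH1 promoter. Among genes with a symbol and a mean of at least 5 CPM, the transcripts with the largest rise in WT TRAP were those of FTIP1, a protein needed for florigen transport from phloem companion cells, iPGAM2, a glycolytic phosphoglycerate mutase, and PSAT, an enzyme of serine synthesis in plastids. FTIP1 (chromosome 5, 2126944 to 2130509, minus strand) rose from 17.3 ± 0.865 CPM in WT Total to 3560 ± 857 CPM in WT TRAP, a log2 fold change of 7.68 ± 0.27 (edgeR adjusted p = 2.27e-08). iPGAM2 (chromosome 3, 2608308 to 2611555, minus strand) rose 49.2-fold, from 163 and 138 CPM to 5760 and 9040 CPM in the 2 libraries (edgeR adjusted p = 1.22e-06). PSAT (chromosome 4, 16904059 to 16905722, plus strand) rose 41.6-fold, from 104 ± 0.951 to 4310 ± 1100 CPM (edgeR adjusted p = 1.18e-07). SERAT3;2, a serine acetyltransferase gene, rose by 3.46 ± 0.30, but lies tail to tail with PSAT and shares its 3′ end on the other strand (16905579 to 16908357), so its reads cannot be told from those of PSAT. Also higher were the subtilase SBT5.4 (log2 fold change 3.78 ± 0.32), the tetraspanin TET14 (11.3-fold), the UDP-glucose epimerase UGE2 (3.21 ± 0.31), the early nodulin-like protein ENODL18 (3.06 ± 0.23) and the clock regulator PRR3 (1.79 ± 0.26). The proteins of FTIP1, PSAT, UGE2 and PRR3 hold the residues DYKxxD, which the FLAG tag also holds, and that of iPGAM2 does not. AT5G35200, an ENTH/ANTH/VHS domain protein chosen after its values were seen, also holds them and rose from 71.8 to 9830 CPM (log2 fold change 7.10 ± 0.32, edgeR adjusted p = 1.23e-07). Chosen in the same way, AT1G19480, a DNA glycosylase family gene with the motif, rose by 7.25 ± 0.45, and AT1G13880, an ELM2 domain gene without it, by 6.01 ± 0.56, both more than iPGAM2. Of the 12 genes with the largest rise at a mean of at least 5 CPM in the WT libraries, 9 encode proteins with the motif. Binding of the FLAG antibody to such proteins, weighed below, is a candidate explanation for these rises. They therefore need not mark cells that use the MSH1 promoter. BXL3, a β-xylosidase of cell walls, fell from 1560 ± 674 to 99.1 ± 15.9 CPM, a log2 fold change of −3.98 ± 0.37 (edgeR adjusted p = 7.91e-05). RR3, a cytokinin response regulator gene (chromosome 2, 17221840 to 17224880, plus strand), fell from 16200 to 1900 CPM (edgeR adjusted p = 4.21e-05), and the antisense locus AT2G09250 inside it fell by a log2 fold change of 3.11, so the source of these reads is uncertain. Small RNA genes among those that fell were AT7SL-1, the RNA of the signal recognition particle, by 6.82-fold, the snoRNA U3B by 5.10-fold and the snRNA AT3G56705 by 6.45-fold, whereas of all 1301 non-coding RNA genes measured 23 were higher and 31 lower (21 and 25 adjusted over the list alone, camera adjusted p = 0.811).

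Among the lists, DNA methylation and RdDM genes were higher in WT TRAP than in WT Total, with a median log2 fold change of 0.26 over 25 genes (camera adjusted p = 0.000665), and adjusted p = 0.91 with an estimated correlation. In this list 3 genes rose and 0 fell over all genes tested, and 4 rose adjusted over the list alone. Organelle DNA maintenance genes were higher at a median of 0.30 over 17 genes (camera adjusted p = 0.0148; adjusted p = 0.91 with an estimated correlation). Of these, 3 were higher and 0 lower, and 6 higher adjusted over the list alone. Among them were the DNA gyrase subunit genes GYRB1, at 1.06 ± 0.17, and GYRA, at 1.34 ± 0.24. The GYRB1 call ended without WT Total 1 (edgeR adjusted p = 0.0963, at 0.98), and that of GYRA without WT Total 1 (0.0816, at 1.39), WT Total 2 (0.0963, at 1.29) or WT TRAP 2 (0.0577, at 0.93). Epidermis and cuticle genes were lower at a median of −0.17 over 36 genes (camera adjusted p = 0.0299; adjusted p = 0.91 with an estimated correlation). Of these, 1 was lower, and 4 lower adjusted over the list alone. The 24 measured seed markers, a list added after values had been seen, had a median of −0.65, with 2 lower and 1 higher, and 5 and 1 adjusted over the list alone. PDF1, a marker of the shoot epidermis, fell by a log2 fold change of 0.88 (edgeR adjusted p = 0.00847), a call that ended without WT Total 1 (edgeR adjusted p = 0.112, at −0.85), WT Total 2 (0.0853, at −0.91) or WT TRAP 1 (0.0598, at −0.74). The epidermis call ended without WT Total 1 (camera adjusted p = 0.161) or WT TRAP 1 (0.904), and the DNA methylation call without WT TRAP 2 (0.106). With a trend on transcript length removed, the DNA methylation list had a median of 0.02 with 1 gene higher, organelle DNA maintenance 0.24 with 2 higher and the epidermis list −0.16 with 1 lower. With edgeR, 1076 of 21202 genes passed, 722 higher and 354 lower in WT TRAP, and of these 322 and 123 differed at least 2-fold. Higher genes had a median transcript length of 2579.5 nt and lower genes 1113 nt, and 721 of the 1076 calls held in the same direction when a trend on length was removed. The count was 167 without WT Total 1, 193 without WT Total 2, 698 without WT TRAP 1, 316 without WT TRAP 2, 642 without msh1 Total 1, 639 without msh1 Total 2, 2310 without msh1 TRAP 1 and 2245 without msh1 TRAP 2.

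**Figure D1:**
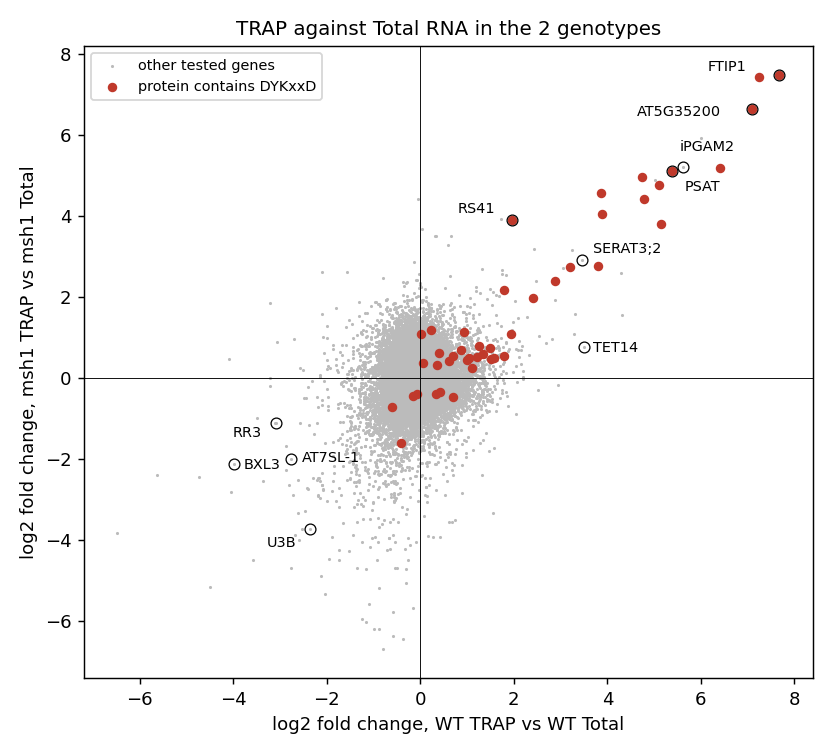
Log2 fold change of TRAP over Total in msh1 against that in WT for each gene tested, with genes whose protein holds the residues DYKxxD in red. FTIP1, AT5G35200, iPGAM2 and PSAT lie above all other labelled genes in both genotypes, and Pearson's r across all 21202 genes is 0.23.

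The comparison of msh1 TRAP with msh1 Total asks the same question in the msh1-labelled plants. FTIP1, iPGAM2 and PSAT again had the largest rise among genes with a symbol and a mean of at least 5 CPM, and 13 of 20 glucosinolate genes and 14 of 27 abscisic acid, drought and cold genes also rose, whereas 28 of 36 epidermis and cuticle genes and 7 of 12 stomatal genes fell. FTIP1 rose from 14.7 and 16.7 CPM in msh1 Total to 2520 and 3130 CPM in msh1 TRAP, a log2 fold change of 7.49 ± 0.27 (edgeR adjusted p = 2.91e-08). iPGAM2 rose from 187 ± 4.8 to 6920 ± 2510 CPM (edgeR adjusted p = 2e-06) and PSAT from 95.5 ± 10.3 to 3280 ± 101 CPM (edgeR adjusted p = 1.38e-07). AT5G35200 and AT1G19480 rose more than iPGAM2, by 6.64 ± 0.31 and 7.44 ± 0.45, as did AT1G13880, by 5.94 ± 0.56. The splicing factor RS41, whose protein also holds DYKxxD, rose from 65.8 to 978 CPM, but overlaps AT5G52045, and its value is uncertain between the 2 loci. IPMI2, an isopropylmalate isomerase subunit, rose 7.31-fold, from 51.4 to 378 CPM (edgeR adjusted p = 7.15e-06), and the glucosinolate genes FMO GS-OX1 and BCAT4 rose by 1.91 ± 0.16 and 1.66 ± 0.17. The cold-induced genes KIN2 and COR47 rose by 1.79 ± 0.23 and 1.75 ± 0.21, the small heat shock protein gene HSP18.2 by 1.75 ± 0.25, the jasmonate repressor gene JAZ1 2.3-fold, the auxin-induced gene IAA2 by 1.45 ± 0.22, and the photosystem I gene PSAH2 by 1.29 ± 0.21. Among clock genes, PRR3 rose by 2.17 ± 0.26 and ELF4 by 1.38 ± 0.26. Genes of cuticle lipid synthesis fell, among them the midchain alkane hydroxylase gene CYP96A15 (log2 fold change −2.54 ± 0.23, edgeR adjusted p = 6.25e-05), the acyltransferase gene PEL3 (−2.08 ± 0.22) and the cutin hydroxylase gene CYP77A6 (−1.84 ± 0.33). CYP77B1 fell from 12.6 to 1.84 CPM (edgeR adjusted p = 0.000173). The myrosinase genes TGG1 and TGG2, active in guard cells and myrosin cells, the first with DYKxxD in its protein, fell 3.03-fold and 3.73-fold. The stomatal receptor kinase gene ERL1 fell 3.92-fold, the phloem sucrose transporter gene SUC2 2.46-fold and the xylem peptidase gene XCP2 1.95-fold. The snoRNA U3B fell 13.3-fold and the snRNAs AT3G56705 and U2.5 fell 14.7-fold and 6.23-fold.

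Across the lists, glucosinolate genes were higher in msh1 TRAP than in msh1 Total at a median of 0.80 over 20 genes (camera adjusted p = 1.78e-08; adjusted p = 0.56 with an estimated correlation). Of these, 13 were higher and 0 lower, and 16 higher adjusted over the list alone. Abscisic acid, drought and cold genes were higher at a median of 0.79 over 27 genes (camera adjusted p = 3.67e-06; adjusted p = 0.11 with an estimated correlation). Of these, 14 were higher and 2 lower, and 15 and 2 adjusted over the list alone. Touch and wound genes were higher at 0.81 over 13 genes (camera adjusted p = 0.000463; adjusted p = 0.56 with an estimated correlation). Of these, 8 were higher and 9 adjusted over the list alone. Photosynthesis genes were higher at 0.40 over 45 genes (camera adjusted p = 0.000173; adjusted p = 0.77 with an estimated correlation). Of these, 16 were higher and 1 lower, and 20 and 1 adjusted over the list alone. Ribosomal protein genes were higher at 0.32 over 16 genes (camera adjusted p = 0.00517; adjusted p = 0.76 with an estimated correlation). Of these, 5 were higher over all genes and adjusted over the list alone. Jasmonate genes were higher at 0.55 over 29 genes (camera adjusted p = 0.0216; adjusted p = 0.76 with an estimated correlation). Of these, 10 were higher and 3 lower, the same as adjusted over the list alone. Clock genes were higher at 0.33 over 22 genes (camera adjusted p = 0.0185; adjusted p = 0.56 with an estimated correlation). Of these, 6 were higher and 1 lower, the same as adjusted over the list alone. Epidermis and cuticle genes were lower at −0.99 (camera adjusted p = 1.59e-12; adjusted p = 0.56 with an estimated correlation). Of these, 28 were lower and 1 higher, and 28 and 2 adjusted over the list alone. The 24 seed markers had a median of −1.33 here, with 9 lower and 11 adjusted over the list alone. Stomatal genes were lower at −0.99 over 12 genes (camera adjusted p = 0.000226; adjusted p = 0.14 with an estimated correlation). Of these, 7 were lower, the same as adjusted over the list alone. DNA methylation and RdDM genes were lower at −0.46 (camera adjusted p = 0.00296; adjusted p = 0.76 with an estimated correlation). Of these, 9 were lower and 11 adjusted over the list alone. The ribosomal call ended without msh1 TRAP 2 (camera adjusted p = 0.196), the clock call without msh1 Total 1 (0.0992) or msh1 TRAP 1 (0.191), and the jasmonate call without msh1 Total 2 (0.393) or msh1 TRAP 2 (0.21). With a trend on transcript length removed, photosynthesis genes had a median of 0.14 with 8 higher and 1 lower, ribosomal protein genes 0.01 with 3 higher, and DNA methylation and RdDM genes −0.08 with 2 lower and 1 higher. The medians of the other called lists then lay between 0.58 and 0.87 in size. With edgeR 5553 genes passed, 2991 higher and 2562 lower in msh1 TRAP, and 953 and 741 of them differed at least 2-fold. With upper-quartile factors the balance turned, to 2757 higher and 2917 lower. The count was 2538 without msh1 Total 1, 2218 without msh1 Total 2 and 3670 without msh1 TRAP 2, and 3725 of the 5553 calls held in the same direction when a trend on transcript length was removed.

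Across genes, the fold changes of TRAP over Total in WT and in msh1 had Pearson's r = 0.23 and Spearman's rho = 0.06, and 50.5% of 21202 genes had the same sign. Genes higher in TRAP in both genotypes numbered 143, where 101.9 would be shared by chance, those lower in both 164, where 42.8 would be, and 103 genes passed in opposite directions. Of the 143, 22 encode proteins with DYKxxD, for which binding of the FLAG antibody is weighed below. Between the genotype comparisons in Total and in TRAP, r was 0.61, rho 0.42 and the share with the same sign 64.2%, with 117 genes higher in both, where 36.1 would be shared by chance, 500 lower in both, where 135.4 would be, and 22 in opposite directions. No library is shared within either pair of comparisons, and genes are not independent replicates. The numbers shared by chance assume that passing in 1 comparison is unrelated to passing in the other. Both came from 1 fit with a common estimate of spread per gene, so an excess is not by itself a repeated finding.

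The comparison of msh1 Total with WT Total asks how transcripts of the stem samples differ between the genotypes. All 24 measured seed markers, a list added after values had been seen, were lower in msh1 Total. The samples may thus differ in seed tissue, as weighed in the closing section. The changes of other genes and lists were not separated from such a difference. In msh1-labelled libraries 9 of 17 genes of the mitochondrial dysfunction response rose, whereas the seed storage genes CRU3 and CRA1, the morning clock genes CCA1 and PRR9 and the light-harvesting genes LHCB2.1 and LHCB2.3 fell. NDB4, an alternative NAD(P)H dehydrogenase of mitochondria, had 2 and 3 counts in WT Total and 115 and 179 counts in msh1 Total (edgeR adjusted p = 0.000041), and AT2G21640, a marker of oxidative stress known as UPOX, rose from 2.55 ± 0.395 to 41.9 ± 4.71 CPM (log2 fold change 4.02 ± 0.23, edgeR adjusted p = 9.74e-06). AT5G09570, a twin cysteine protein gene induced by mitochondrial stress, rose from 1.47 to 18.6 CPM, with 3.65 ± 0.31 (edgeR adjusted p = 7.73e-05). The hypoxia-responsive factor gene ERF71 had 1 and 2 counts in WT Total and 29 and 32 counts in msh1 Total (edgeR adjusted p = 0.00141). BT2, a BTB and TAZ domain protein gene, rose 6.32-fold, from 51.7 and 78.9 CPM to 560 and 268 CPM in the 2 libraries (edgeR adjusted p = 0.00157). Smaller rises were those of the sulfotransferase gene SOT12 (2.91-fold), the auxin transporter gene ABCB4 (2.62-fold) and the stress tolerance gene OXS3 (2.51-fold). The seed storage globulin genes CRU3 and CRA1 fell, CRU3 (chromosome 4, 14087556 to 14089796, plus strand) from 646 ± 104 to 51 ± 29.4 CPM (edgeR adjusted p = 0.000522) and CRA1 from 597 ± 90.3 to 54.1 ± 30.6 CPM (edgeR adjusted p = 0.000706). Their log2 fold changes were −3.66 ± 0.43 and −3.46 ± 0.43. The albumin gene SESA3 fell 12.1-fold and the oleosin gene OLEO1 11.6-fold. The gibberellin oxidase gene GA20OX3 (log2 fold change −3.59 ± 0.38), the peroxisomal citrate synthase gene CSY1 (−3.46 ± 0.37), the methylesterase gene MES4 (−3.57 ± 0.39) and the β-glucosidase gene BGLU29 (−3.44 ± 0.45) fell with them. The morning clock genes CCA1 and PRR9 had log2 fold changes of −2.99 ± 0.30 and −3.35 ± 0.37, CCA1 falling from 22.9 to 2.83 CPM (edgeR adjusted p = 0.000226). The light-harvesting genes LHCB2.1 and LHCB2.3, which share reads with close copies, fell too (log2 fold change −1.92 ± 0.23 and −1.83 ± 0.28). So did the chaperone gene HSP70 (−1.22 ± 0.18) and the galactinol synthase gene GolS2 (−1.38 ± 0.19). Some calls ended in the smaller fits without 1 library, where the folds kept their sign. DFR, of anthocyanin synthesis, was at −2.14 ± 0.39 (edgeR adjusted p = 0.00849), and its call ended without WT Total 1 (edgeR adjusted p = 0.0888, at −1.5) or msh1 Total 1 (0.0981, at −2.06). The ovule identity gene STK was at −1.76, and its call ended without WT Total 1 (edgeR adjusted p = 0.106, at −1.34) or msh1 Total 1 (0.125, at −1.55).

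In msh1 Total the mitochondrial dysfunction list was higher at a median of 0.94 over 17 genes (camera adjusted p = 4.55e-07; adjusted p = 0.2 with an estimated correlation). Of these, 9 were higher and 0 lower, and 10 and 2 adjusted over the list alone. Organelle DNA maintenance genes were higher at 0.30 (camera adjusted p = 4.23e-06; adjusted p = 0.2 with an estimated correlation). Of these, 3 were higher and 5 adjusted over the list alone. The 3 were MSH1 itself, which is on this list, WHY3 and AT1G30680. The calls of WHY3 and AT1G30680 ended when any 1 of the Total libraries was left out. Their values there stayed between 0.69 and 0.89 for WHY3 and between 0.64 and 0.77 for AT1G30680. Cell division genes were higher at 0.25 over 27 genes (camera adjusted p = 0.000925; adjusted p = 0.53 with an estimated correlation) and ribosomal protein genes at 0.28 (camera adjusted p = 0.00947; adjusted p = 0.56 with an estimated correlation), and in both 0 genes passed in edgeR, also adjusted over the list alone. In each of these 1 gene was higher at an unadjusted p under 0.05, and 0 genes passed with DESeq2 or limma-voom. Glucosinolate genes were lower at −0.60 (camera adjusted p = 4.84e-08; adjusted p = 0.25 with an estimated correlation). Of these, 8 were lower and 12 adjusted over the list alone. Lignin genes were lower at −0.58 over 13 genes (camera adjusted p = 4.84e-08; adjusted p = 0.23 with an estimated correlation). Of these, 5 were lower and 11 adjusted over the list alone. The calls of PAL2, 4CL2 and OMT1, the largest changes among them, ended when any 1 of the Total libraries was left out. Their values there stayed between −0.92 and −0.68, −0.84 and −0.53, and −0.87 and −0.53. Cambium, xylem and secondary wall genes were lower at −0.36 over 29 genes (camera adjusted p = 2.16e-06; adjusted p = 0.25 with an estimated correlation). Of these, 2 were lower, FRA8 and GAUT12, and 11 adjusted over the list alone. Both calls ended without WT Total 1, WT Total 2 or msh1 Total 1. There FRA8 stood at −0.73, −0.71 and −0.59 and GAUT12 at −0.69, −0.62 and −0.47. The call of FRA8 also ended with DESeq2 (adjusted p = 0.0784). Abscisic acid, drought and cold genes were lower at −0.41 (camera adjusted p = 4.84e-08; adjusted p = 0.069 with an estimated correlation). Of these, 7 were lower, and 13 lower and 1 higher adjusted over the list alone. Clock genes were lower at −0.54 (camera adjusted p = 4.35e-05; adjusted p = 0.23 with an estimated correlation). Of these, 8 were lower, and 9 lower and 1 higher adjusted over the list alone. Floral organ genes were lower at −0.73 over 15 genes (camera adjusted p = 1.59e-06; adjusted p = 0.25 with an estimated correlation). Of these, 5 were lower and 9 adjusted over the list alone. Flavonoid genes were lower at −0.67 over 16 genes (camera adjusted p = 1.19e-05; adjusted p = 0.25 with an estimated correlation). Of these, 5 were lower and 6 adjusted over the list alone. Beside these, the 24 seed markers had a median of −3.19, with 19 lower and 23 adjusted over the list alone. Heat shock genes were lower at −0.63 over 18 genes (camera adjusted p = 7.61e-05; adjusted p = 0.23 with an estimated correlation). Of these, 2 were lower and 5 adjusted over the list alone. Touch and wound genes were lower at −0.58 (camera adjusted p = 0.00257; adjusted p = 0.37 with an estimated correlation). Of these, 1 was lower and 7 adjusted over the list alone. Epidermis genes were lower at −0.13 (camera adjusted p = 0.015; adjusted p = 0.75 with an estimated correlation), with 0 past the threshold in edgeR, also adjusted over the list alone, 1 lower at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom. The touch call ended without WT Total 2 (camera adjusted p = 0.216) and the epidermis call without WT Total 1 (0.294) or msh1 Total 1 (0.082). Photosynthesis genes were not called (camera adjusted p = 0.54), with a median of 0.04 over 45 genes, 3 lower and 0 higher, and 6 lower and 1 higher adjusted over the list alone. Salicylic acid and defence genes (camera adjusted p = 0.655, 2 lower, 3 adjusted over the list alone), auxin genes (0.429, 1 lower, 2 adjusted over the list alone), phloem genes (0.72, 0 passing, the same as adjusted over the list alone) and non-coding RNA genes (0.72) were not called by camera. Of the phloem genes 2 were lower at an unadjusted p under 0.05, and 0 passed with DESeq2 or limma-voom. Of 1301 non-coding RNA genes measured, 7 were higher and 21 lower, and 3 and 14 adjusted over the list alone. With edgeR 824 genes passed, 174 higher and 650 lower in msh1 Total, of which 79 and 483 differed at least 2-fold. The count was 304 without WT Total 1, 390 without WT Total 2, 219 without msh1 Total 1, 492 without msh1 Total 2, 1650 without msh1 TRAP 1 and 1616 without msh1 TRAP 2.

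**Figure D2:**
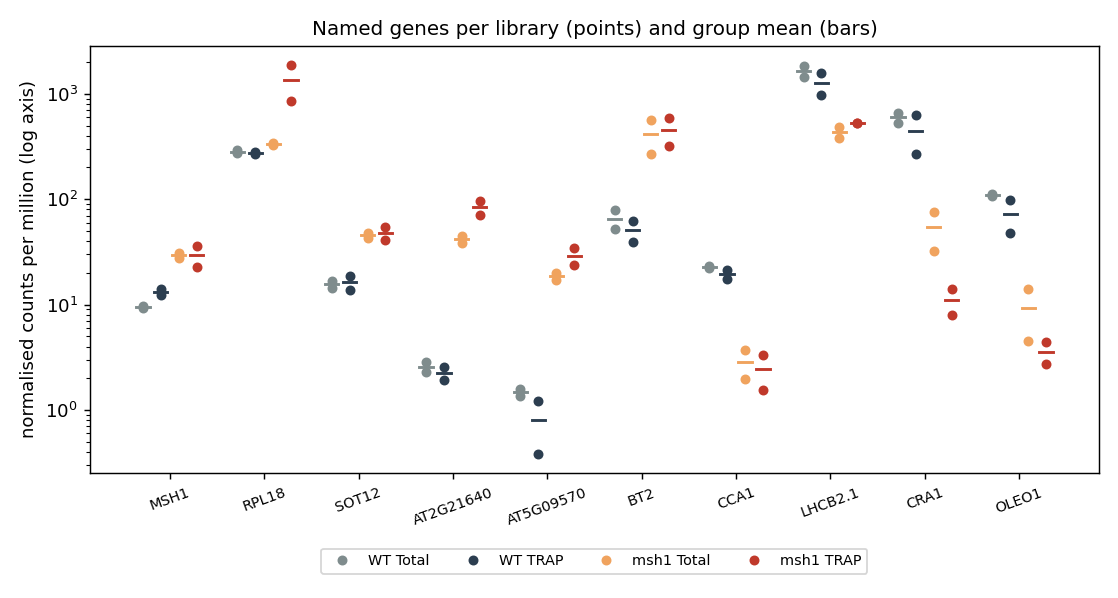
TMM-normalised CPM (log axis) of 10 genes in each of the 8 libraries, with points for libraries and bars for the mean of each group of 2. MSH1, SOT12, AT2G21640, AT5G09570 and BT2 are higher and CCA1, LHCB2.1, CRA1 and OLEO1 lower in both msh1-labelled groups, and RPL18 is highest in msh1 TRAP.

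The comparison of msh1 TRAP with WT TRAP asks how RNA purified with tagged ribosomes differs between the genotypes. The 8 libraries include no pull-down from plants without the tag, and RPL18 was higher in msh1 TRAP than in WT TRAP. A genotype difference in the amount of tagged protein or in background RNA was therefore not tested. Nor were the changes below separated from a possible difference in seed tissue, weighed in the closing section. The mitochondrial stress genes AT2G21640, AT5G09570 and NDB4 rose in TRAP too, as did 12 of the 16 measured genes of the partial ribosomal protein list. The seed storage genes CRU3 and CRA1, 28 of 36 epidermis and cuticle genes and 7 of 13 lignin genes fell. AT2G21640 rose from 2.25 ± 0.453 CPM in WT TRAP to 83.4 ± 18.9 CPM in msh1 TRAP, a log2 fold change of 5.23 ± 0.25 (edgeR adjusted p = 1.06e-06), and AT5G09570 from 0.8 to 29 CPM (edgeR adjusted p = 1.67e-05). NDB4 had 0 and 3 counts in WT TRAP and 84 and 102 counts in msh1 TRAP (edgeR adjusted p = 3e-05), and the NAC factor gene NAC044 rose from 0.294 to 10.4 CPM (edgeR adjusted p = 3e-05). BT2 rose 8.94-fold (edgeR adjusted p = 9.8e-05), the sulfur deficiency gene ATSDI1 9.99-fold, from 4.46 to 43.5 CPM (edgeR adjusted p = 0.000175), and PCC1, a pathogen-induced gene, 6.32-fold. KIN2 and COR47 rose by 2.33 ± 0.23 and 1.91 ± 0.21, the defence factor gene WRKY18 by 1.84 ± 0.39, and the auxin-induced genes IAA2 and IAA19 by 1.68 ± 0.22 and 1.70 ± 0.32. The plastocyanin gene DRT112, the Rubisco small subunit gene RBCS1B and PSAH2 rose by 1.52, 1.48 and 1.45, and the ribosomal protein gene AT4G25890 by 1.64 log2 units. CRU3 and CRA1 fell 40.8-fold each, CRU3 from 399 ± 243 to 9.76 ± 0.975 CPM and CRA1 from 448 ± 253 to 11 ± 4.25 CPM (edgeR adjusted p = 3.4e-05 for both). CRU2 fell 37.0-fold and TT10, a laccase-like gene of seed coat browning, 25.5-fold, to 0.985 CPM. CCA1 (log2 fold change −3.01 ± 0.33), PRR9 (−2.85 ± 0.37) and HSP70 (−1.45 ± 0.19) fell, whereas the evening gene ELF4 rose by 1.92 ± 0.28. Among cuticle genes CYP77A6 (−2.32 ± 0.34) and CYP96A15 (−2.15 ± 0.23) fell, and PEL3 fell 3.89-fold. The lignin genes PAL2 (−1.36 ± 0.16) and C4H (−1.24 ± 0.15) and the secondary wall cellulose synthase genes CESA4 (−1.83 ± 0.20) and IRX3 (−1.41 ± 0.17) fell, whereas WOX4, a cambium regulator, rose by 1.41 ± 0.28. The RdDM genes AGO9 (−2.55 ± 0.39), NRPD1B (−1.62 ± 0.21) and AGO4 (−1.47 ± 0.24) fell. So did the flavonoid genes TT7 (−2.84 ± 0.43) and DFR (−2.28 ± 0.44) and the pollen tube pectinesterase gene VGD1 (−2.28 ± 0.26), and STK fell 5.28-fold.

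Ribosomal protein genes were higher in msh1 TRAP than in WT TRAP, at a median of 1.01 over 16 genes (camera adjusted p = 2.76e-05; adjusted p = 0.54 with an estimated correlation). Of these, 12 were higher and 0 lower, the same as adjusted over the list alone. With a length trend removed their median was 0.44 with 7 higher. Jasmonate genes were higher at 0.83 (camera adjusted p = 0.0214; adjusted p = 0.58 with an estimated correlation). Of these, 13 were higher and 3 lower, and 15 and 3 adjusted over the list alone. Mitochondrial dysfunction genes were higher at 0.52 (camera adjusted p = 0.0139; adjusted p = 0.54 with an estimated correlation). Of these, 9 were higher and 3 lower, the same as adjusted over the list alone. Epidermis genes were lower at −0.89 (camera adjusted p = 3.69e-08; adjusted p = 0.54 with an estimated correlation). Of these, 28 were lower and 2 higher, and 29 and 4 adjusted over the list alone. DNA methylation and RdDM genes were lower at −0.79 (camera adjusted p = 0.000153; adjusted p = 0.54 with an estimated correlation). Of these, 13 were lower and 14 adjusted over the list alone. With a length trend removed the median of this list was −0.14, with 5 lower and 2 higher. Cambium, xylem and secondary wall genes were lower at −0.50 (camera adjusted p = 0.00233; adjusted p = 0.54 with an estimated correlation). Of these, 15 were lower and 2 higher, the same as adjusted over the list alone. Lignin genes were lower at −0.58 (camera adjusted p = 0.00626; adjusted p = 0.54 with an estimated correlation). Of these, 7 were lower and 1 higher, the same as adjusted over the list alone. Floral organ genes were lower at −0.61 (camera adjusted p = 0.00455; adjusted p = 0.54 with an estimated correlation). Of these, 8 were lower, the same as adjusted over the list alone. Flavonoid genes were lower at −0.89 (camera adjusted p = 0.0196; adjusted p = 0.58 with an estimated correlation). Of these, 9 were lower, the same as adjusted over the list alone. The 24 seed markers had a median of −4.25, with 20 lower, the same as adjusted over the list alone. The flavonoid call ended without WT TRAP 2 (camera adjusted p = 0.0548) or msh1 TRAP 1 (0.075), and the jasmonate call without msh1 TRAP 2 (0.105). Photosynthesis genes split, with 25 higher and 13 lower, the same as adjusted over the list alone (camera adjusted p = 0.0688), and all 13 lower ones encode light-harvesting proteins. With a length trend removed the majority turned, to 11 higher and 17 lower, and the median fell from 0.56 to 0.10. Clock genes (camera adjusted p = 0.0688, 11 lower and 4 higher, 12 and 4 adjusted over the list alone) and stomatal genes (0.0688, 5 lower and 2 higher, 6 and 2 adjusted over the list alone) were not called. Neither were salicylic acid genes (0.178, 6 higher and 2 lower), phloem genes (0.997, 5 higher and 6 lower), both the same as adjusted over the list alone, and auxin genes (0.997, 6 higher and 5 lower, 6 and 8 adjusted over the list alone). Heat shock genes had a median of 0.17 but ranked lower in camera (camera adjusted p = 0.967), with 3 higher and 4 lower, and 4 and 6 adjusted over the list alone. The list of KIN2 and COR47, abscisic acid, drought and cold, was not called (camera adjusted p = 0.0944), with a median of 0.10, 11 higher and 5 lower, the same as adjusted over the list alone. Also not called were glucosinolate genes (0.0896, 6 higher and 1 lower), touch and wound genes (0.0667, 3 higher) and organelle DNA maintenance genes (0.769, 6 higher and 7 lower), each the same as adjusted over the list alone. Nor were cell division genes (0.301, 6 higher and 1 lower, 3 and 0 adjusted over the list alone) and non-coding RNA genes (0.997, 179 higher and 171 lower, 155 and 138 adjusted over the list alone). With a length trend removed, 125 non-coding RNA genes were higher and 253 lower, at a median of −0.19. With edgeR 8818 genes passed, 4400 higher and 4418 lower in msh1 TRAP, so that neither direction prevailed, and 2029 and 1952 of these differed at least 2-fold. Higher genes had a median transcript length of 1194 nt and lower genes 2369.5 nt, and with a length trend removed 5202 of the 8818 calls, 59%, held in the same direction, whereas without WT TRAP 2 the count was 5835.

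**Figure D3:**
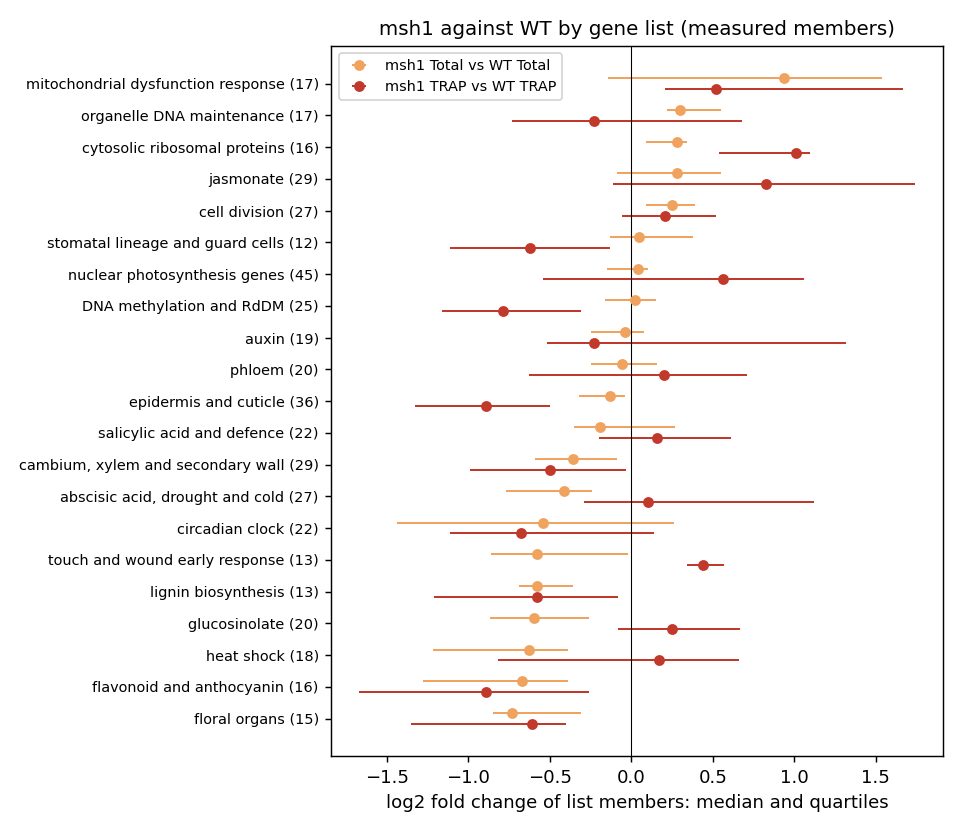
Median and quartiles of the log2 fold change of msh1 over WT for the members of 21 gene lists, in Total and in TRAP, with the number of genes measured in brackets. The median of mitochondrial dysfunction genes lies above 0 in both fractions, with a lower quartile of −0.14 in Total, and the medians of floral organ, flavonoid and lignin genes lie below 0 in both.

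The interaction asks whether the msh1 difference was larger in TRAP than in Total. It was more positive in TRAP for 7 of 20 glucosinolate genes and 11 of 27 abscisic acid, drought and cold genes, and more negative for 18 of 36 epidermis and cuticle genes, 5 of 12 stomatal genes and 7 of 17 organelle DNA maintenance genes. With a trend on transcript length removed these counts were 7, 10, 13, 3 and 2 in the same order. IPMI2 stood at 91.1 CPM in WT Total, 83.3 in WT TRAP, 51.4 in msh1 Total and 378 in msh1 TRAP (edgeR adjusted p = 0.000599), the largest positive interaction among genes with a symbol and a mean of at least 5 CPM. Next was the glutathione S-transferase gene GSTU20 at 2.75 ± 0.25 (edgeR adjusted p = 0.000599), with 465, 360, 307 and 1600 CPM in the same order of groups. The cytochrome b5 gene CB5-C had 2.65 ± 0.26, the metallothionein gene MT2B 2.44 ± 0.23 and the methionine sulfoxide reductase gene PMSR2 2.32 ± 0.23. COR47 had 2.23 ± 0.29, KIN2 2.21 ± 0.32, HSP18.2 1.90 ± 0.35 and the cambium regulator gene WOX4 1.89 ± 0.39. The glucosinolate genes FMO GS-OX1 and BCAT4 had 1.87 ± 0.22 and 1.73 ± 0.24. RPL18 had 2.06 ± 0.39 (edgeR adjusted p = 0.00597). CYP77B1 had −3.11 ± 0.39 (edgeR adjusted p = 0.0019), with 10.1 CPM in WT Total, 12.8 in WT TRAP, 12.6 in msh1 Total and 1.84 in msh1 TRAP. The cell wall invertase gene cwINV4 had −2.43 ± 0.46 and the plastid chaperone gene cpHsc70-2 −2.19 ± 0.33, with 263, 941, 300 and 235 CPM in the same order of groups. LOX2, of jasmonate synthesis, had −2.04 ± 0.31 (edgeR adjusted p = 0.00249). Cuticle genes CYP96A15 and CYP86A4 had −1.79 ± 0.31 and −1.64 ± 0.34, the myrosinase gene TGG2 −1.48 ± 0.26, the sieve element gene SEOa −1.58 ± 0.33, GYRB1 −1.34 ± 0.25 and AT1G30680, the organelle DNA helicase Twinkle, −1.43 ± 0.23.

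In the interaction, 3312 genes passed with edgeR, 1910 positive and 1402 negative, of which 1326 and 765 differed at least 2-fold. Positive genes had a median transcript length of 1143 nt and negative genes 2864 nt. With a trend on length removed 1585 genes passed, and 1264 of the first 3312 held in the same direction. Of the 69 interaction calls that the naming rule gave, 27 were ended by this. Among them were the DNA methylation gene MET1 (edgeR adjusted p = 0.00743, then 0.117 at −0.76), and the DNA glycosylase gene DME (0.00396 at −1.29, then 0.254 at −0.38). The count was 1176 without WT Total 1, 1009 without WT Total 2, 1508 without WT TRAP 2, 1376 without msh1 Total 1, 1247 without msh1 Total 2 and 5575 without msh1 TRAP 1. Without msh1 TRAP 2 the balance turned, to 1487 positive and 1515 negative. Camera called 6 lists higher and 4 lower in the interaction, and the lowest adjusted p was 0.11 with an estimated correlation.

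**Figure D4:**
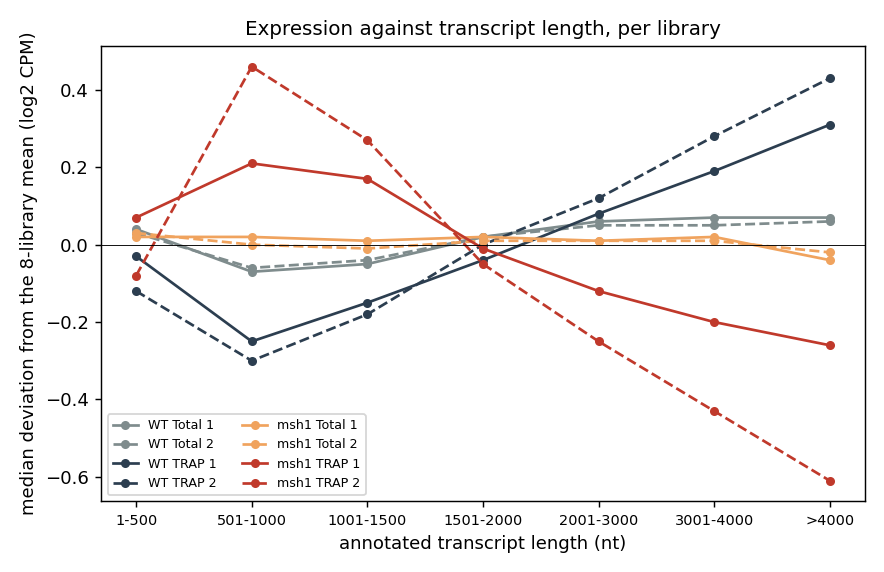
Median deviation of log2 CPM from the mean of all 8 libraries over 7 bins of transcript length, with 1 line per library (solid for replicate 1, dashed for replicate 2). Above 4000 nt WT TRAP stands at 0.31 and 0.43 and msh1 TRAP at −0.26 and −0.61 and, among transcripts of up to 1000 nt in the next to shortest bin, the order is the opposite.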

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

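The results here are those where the interaction test showed that the msh1 difference in TRAP was not the same as that in Total. The fits with a length or GC trend removed were added after the data were seen, and the tests of the interaction calls, of the calls that ended and of the calls kept without msh1 TRAP 2 were chosen only after their results were seen. Among named genes with a more positive msh1 difference in TRAP were IPMI2 at 3.0, GSTU20 at 2.75, CB5-C at 2.65, MT2B at 2.44 and PMSR2 at 2.32 (edgeR adjusted p at most 0.000969). DR4, annotated as drought-repressed, had 2.37 and the protease inhibitor gene KTI1 2.24. GSTF11, at 2.42, overlaps NAC045, so its value is uncertain between these loci. RPL18 had 2.06 (edgeR adjusted p = 0.00597), which includes any reads of the transgene. More negative in TRAP were MEE48 at −4.22, CYP77B1 at −3.11, the seed vicilin gene PAP85 at −2.97, the germline Argonaute gene AGO5 at −2.88, the stomatal density gene SDD1 at −2.44, cwINV4 at −2.43, the pollen exchanger gene CHX23 at −2.28 and cpHsc70-2 at −2.19. MEE48 had 3 and 5 counts in msh1 TRAP and PAP85 5 and 2, so their sizes are poorly fixed. The call of AGO5 ended without msh1 Total 2 (edgeR adjusted p = 0.053, at −2.42) and that of SDD1 without WT TRAP 2 (0.0566, at −1.85). The call of CHX23 ended without WT Total 1 (edgeR adjusted p = 0.0637), WT Total 2 (0.066), WT TRAP 1 (0.0587), WT TRAP 2 (0.0645) or msh1 Total 2 (0.0745), with a length trend removed (0.0575), and with DESeq2 (adjusted p = 0.11), while its value stayed between −2.36 and −1.91. That of PAP85 ended without WT Total 1 (edgeR adjusted p = 0.0699), WT Total 2 (0.064), WT TRAP 2 (0.0806), msh1 Total 2 (0.14), msh1 TRAP 1 (0.0589) or msh1 TRAP 2 (0.161), with a length trend removed (0.0564), and with limma-voom (adjusted p = 0.142), while its value stayed between −3.78 and −2.15. That of KTI1 ended without WT Total 1 (edgeR adjusted p = 0.0502), WT Total 2 (0.147), WT TRAP 1 (0.0558), WT TRAP 2 (0.159), msh1 Total 1 (0.0901), msh1 Total 2 (0.0952) or msh1 TRAP 2 (0.134), with a length trend removed (0.0969), and with limma-voom (adjusted p = 0.0785), while its value stayed between 1.2, without msh1 TRAP 2, and 2.58.

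As lists, touch and wound genes had a median interaction of 1.13 (camera adjusted p = 0.000195; adjusted p = 0.51 with an estimated correlation), with 3 genes positive and 8 adjusted over the list alone. Abscisic acid, drought and cold genes had 0.84 (camera adjusted p = 1.78e-06; adjusted p = 0.11 with an estimated correlation), with 11 positive and 1 negative, and 13 and 1 adjusted over the list alone. Glucosinolate genes had 0.71 (camera adjusted p = 3.59e-06; adjusted p = 0.51 with an estimated correlation), with 7 positive and 10 adjusted over the list alone. Ribosomal protein genes had 0.65 (camera adjusted p = 0.000296; adjusted p = 0.52 with an estimated correlation), with 4 positive and 8 adjusted over the list alone. Jasmonate genes had 0.64 (camera adjusted p = 0.0328; adjusted p = 0.74 with an estimated correlation), with 3 positive and 1 negative, the same as adjusted over the list alone. Photosynthesis genes had 0.51 (camera adjusted p = 0.00473; adjusted p = 0.88 with an estimated correlation), with 10 positive and 13 adjusted over the list alone. Stomatal genes had −0.89 (camera adjusted p = 0.01; adjusted p = 0.51 with an estimated correlation), with 5 negative, the same as adjusted over the list alone. Epidermis and cuticle genes had −0.81 (camera adjusted p = 6.93e-08; adjusted p = 0.52 with an estimated correlation), with 18 negative and 21 adjusted over the list alone. DNA methylation and RdDM genes had −0.80 (camera adjusted p = 3.59e-06; adjusted p = 0.51 with an estimated correlation), with 9 negative and 14 adjusted over the list alone. Organelle DNA maintenance genes had −0.48 (camera adjusted p = 0.00821; adjusted p = 0.51 with an estimated correlation), with 7 negative, the same as adjusted over the list alone. With a length trend removed the median of DNA methylation genes was −0.22 with 0 past the threshold, that of photosynthesis genes 0.11 with 1 positive, that of ribosomal protein genes 0.14 with 1 positive, that of touch genes 0.87 with 1 positive and that of organelle DNA maintenance genes −0.50 with 2 negative. Epidermis genes then had −0.58 with 13 negative, stomatal genes −0.73 with 3 negative, jasmonate genes 0.58 with 2 positive and 1 negative, abscisic acid genes 0.68 with 10 positive and glucosinolate genes 0.77 with 7 positive. The photosynthesis call ended without WT TRAP 1 (camera adjusted p = 0.128) or msh1 TRAP 2 (0.211), and the jasmonate call without WT Total 2 (0.167), WT TRAP 2 (0.104), msh1 Total 2 (0.39) or msh1 TRAP 2 (0.211). Beside these lists, the 24 seed markers had a median interaction of −0.70, with 2 negative and 0 adjusted over the list alone.

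In msh1 TRAP against WT TRAP 8818 genes passed and in the interaction 3312, and across genes the fold change fell with transcript length, with Spearman's rho of −0.44 and −0.45. A genotype difference in the amount of tagged protein or in background RNA was not tested for either set of calls. Of the 8818 calls, 5202 (59%) held in the same direction with a length trend removed and 7521 (85.3%) with a GC trend removed. Without msh1 TRAP 2, 6401 (72.6%) held. This argues against a smooth trend on length, a smooth trend on GC or that library as the whole cause. The shares for length and GC met neither bound stated for these calls before those fits (under 50% or over 90% kept), so by those bounds they were undecided. Effects of length or GC apart from the smooth trend, and both trends together, were not tested. Of the 3312 interaction calls 38.2% held with a length trend removed, below that 50%, and this was judged by looser bounds written after the result (under 5% or over 20% kept), so it argues only against length as the cause of every interaction call and leaves open that a length trend may account for most of them. The 3616 calls between genotypes that ended had a median log2 fold change of 0.76 in size before and 0.31 in their earlier direction after (quartiles 0.15 to 0.46), a value taken in place of the 90.7% that kept their sign after that share was seen, but both values are largely fixed by picking genes whose call ended, so neither says what ended the calls. For these 3616 calls a technical length effect, such as RNA breakage that differed between TRAP samples, cannot be told apart from a genotype difference, because length correlated with the level at rho of 0.33 and 0.41 in both WT TRAP libraries and −0.29 and −0.39 in both msh1 TRAP libraries, and the genotype difference itself stays open as untested.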

How the results depend on the processing

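The fits with a length or GC trend removed were added after the data were seen, and the other settings here were not. The naming rule gave 309 calls of genes, more than the text names, and none changed direction under any setting run. Of these, 22 were no longer past the threshold with DESeq2, 2 with RLE factors, 3 with upper-quartile factors, 8 with limma-voom, 24 with the replicate number as a term, 54 with a length trend removed and 22 with a GC trend removed. Of the calls that had a value there, 5 were lost with at least 5 CPM in 2 libraries, where some genes were not tested, and 16 with only the 4 libraries compared, where the interaction has no value. Among the genes the rule gave, the call held under every setting that gave it a value for 14 of 34 in WT TRAP against WT Total, 45 of 76 in msh1 TRAP against msh1 Total, 23 of 52 between genotypes in Total, 63 of 78 in TRAP and 30 of 69 in the interaction. All 46 list calls held with RLE factors and with the replicate number as a term, and all 46 were lost with an estimated correlation.

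Counts of genes stayed within 1.5 times the reported ones with DESeq2, RLE or upper-quartile factors, limma-voom, at least 5 CPM in 2 libraries and the replicate number as a term, for all 5 comparisons. The replicate number gave 742, 4871, 656, 8285 and 2600 genes in the order above, and its labels were not shown to pair samples, since residuals of equal number correlated at −0.24 to 0.08 over 6 pairs of groups. The balance between directions turned for msh1 TRAP against msh1 Total with upper-quartile factors (2757 higher and 2917 lower, against 2991 and 2562) and for the interaction without msh1 TRAP 2 (1487 and 1515, against 1910 and 1402). Between genotypes in TRAP, at 4400 higher and 4418 lower, it turned with DESeq2 (3790 and 3732), the replicate number as a term (4153 and 4132), a length trend removed (3333 and 3235) and only the 4 libraries compared (3476 and 3295). It turned there too without WT Total 1 (3939 and 3874), WT Total 2 (3962 and 3890), WT TRAP 2 (3166 and 2669), msh1 Total 1 (4096 and 3991), msh1 Total 2 (4078 and 4004) or msh1 TRAP 1 (5160 and 4357). Without a filter on low counts, WT TRAP against WT Total gave 2011 genes in place of 1076 and msh1 Total against WT Total 1770 in place of 824. With only the 4 libraries compared, WT TRAP against WT Total gave 1871, msh1 TRAP against msh1 Total 3548 in place of 5553, and msh1 Total against WT Total 2708. With a length trend removed the interaction gave 1585 in place of 3312. The cause was not tested.

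Leaving out 1 library gave 167 (without WT Total 1) to 2310 genes (without msh1 TRAP 1) for WT TRAP against WT Total, which also had 193 without WT Total 2, 698 without WT TRAP 1, 316 without WT TRAP 2, 642 and 639 without msh1 Total 1 and 2, and 2245 without msh1 TRAP 2. For msh1 TRAP against msh1 Total the range was 2218 (without msh1 Total 2) to 7114 (without msh1 TRAP 1), with 2538 without msh1 Total 1 and 3670 without msh1 TRAP 2. Between genotypes in Total it was 219 (without msh1 Total 1) to 1650 (without msh1 TRAP 1), with 304 and 390 without WT Total 1 and 2, 492 without msh1 Total 2 and 1616 without msh1 TRAP 2. Between genotypes in TRAP it was 5835 (without WT TRAP 2) to 9517 (without msh1 TRAP 1). For the interaction it was 1009 (without WT Total 2) to 5575 (without msh1 TRAP 1), with 1176 without WT Total 1, 1508 without WT TRAP 2, and 1376 and 1247 without msh1 Total 1 and 2. Fewer libraries leave fewer degrees of freedom. All 4 groups share 1 estimate of the spread, and the 2 msh1 TRAP libraries differed most from each other. Chi-square per gene between replicates was 17.58 there, 9.43 in WT TRAP, 7.04 in WT Total and 5.21 in msh1 Total. Leaving 1 of that pair out takes this spread from the estimate, but its share in the raised counts was not tested. With only the 4 libraries compared, the genotype counts were 2708 in Total and 6771 in TRAP, against 824 and 8818. The gap between fractions thus depends on the shared fit.

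Across genes, Pearson's r between the TRAP and Total differences of WT and msh1 was 0.23, and 0.33 with a length trend removed, 0.26 with a GC trend removed and 0.16 to 0.27 without 1 library. That between the genotype differences in Total and in TRAP was 0.61, and 0.59 with at least 5 CPM in 2 libraries, 0.65 with a length trend removed, 0.62 with a GC trend removed and 0.56 to 0.60 without 1 library. TMM without organelle genes was not run, since those loci held 0 counts. Depth limits genes near 3 counts, 0.22 to 0.396 CPM, such as NDB4 and ERF71 in WT.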

Other observations

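The tests of motif position, of proteins with YKxxD alone and of the share of motif genes higher in both genotypes, and all tests of seed markers, were chosen only after the results were seen. Several loci chosen after their values were seen differed between genotypes in both fractions. AT2G04050, a MATE efflux family gene, stood at 0.48 CPM in WT Total, 0.625 in WT TRAP, 11.6 in msh1 Total and 8.5 in msh1 TRAP. AT5G52940 stood at 1.87, 2.76, 20.9 and 26.4 CPM in the same order, and AT2G41730 at 2.33, 1.87, 16.8 and 31.6 CPM. AT2G01422 stood at 13.4 and 19 CPM in WT Total and WT TRAP, and at 0.165 and 0.0637 CPM in msh1 Total and msh1 TRAP, near the floor. Of the alternative oxidase genes, AOX1A rose by 0.77 ± 0.16 in msh1 Total (edgeR adjusted p = 0.0169), and AOX1D had −0.48 (edgeR adjusted p = 0.751). A close copy of RPL18, AT5G27850, stood at 264, 272, 338 and 395 CPM over the same groups and had an interaction of 0.18 (edgeR adjusted p = 0.64).

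Of 369 snoRNA and snRNA loci, a list added after values had been seen and given no set test, 94 were measured. In WT the median log2 fold change of TRAP over Total was −0.86, where 10 were lower, 0 higher and 84 did not pass (13 lower adjusted over the list alone). In msh1 the median was −0.87, with 29 lower and 5 higher (31 and 5 adjusted over the list alone).

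iPGAM2 and AT5G35200 together held 1.02 to 1.819% of gene counts in the TRAP libraries of both genotypes and 0.023 to 0.028% in the Total libraries. For AT5G35200, with the other motif genes, expression in cells that use the MSH1 promoter is argued against as the whole cause, since 22 of 44 tested genes whose protein holds DYKxxD (50%) were higher in TRAP in both genotypes, against 116 of 19856 others (0.58%). A candidate explanation for AT5G35200 and other motif genes, such as FTIP1 and PSAT, is that the FLAG antibody bound nascent proteins with FLAG-like residues. Of 27444 nuclear proteins 55 hold these residues. The 43 tested motif genes other than AT5G35200 had a median of 1.34 in WT (95th percentile of matched random sets 0.09) and 0.74 in msh1 (0.21). In WT the fold change rose with the codons after the motif (Spearman's rho across genes 0.47, two-sided permutation p = 0.0013). The protein of AT5G35200 holds the motif and that of iPGAM2 does not. For iPGAM2 both explanations stay open, since the share above does not bear on a gene without the motif. The 665 genes with YKxxD alone had a median of 0.09 in WT, above −0.03 in random sets, and −0.15 in msh1, below 0.04. This test was first read in WT alone and then required both genotypes. Its random sets were not matched on transcript length, with which TRAP over Total correlated at Spearman's rho of 0.32 in WT and −0.32 in msh1. A length trend could give these signs by itself, so the YKxxD test cannot decide for iPGAM2.

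Seed transcripts were lower in msh1-labelled libraries, with all 24 measured seed markers lower in Total and 23 in TRAP, and the most abundant, CRU3 and CRA1, at 646 and 597 CPM in WT Total and 51 and 54.1 CPM in msh1 Total. A change of storage protein and oleosin genes alone is argued against, since the 11 other markers had a median of −2.90 (quartiles −3.25 to −1.38), among them LEC1 at −2.98 and ABI3 at −3.37. More seed tissue in the WT-labelled samples may account for the pattern, since 79.2% of the markers lay within 1 log2 unit of their median of −3.19, and no step named in the labels would remove seeds from the stems. The list was written after marker values were seen, it shares 0 genes with the other lists, and how many of its genes stems express on their own was not measured. Only 24 of its 30 genes passed the filter on counts, which a gene low in msh1 can pass through the WT libraries alone. The shares and medians of the markers may thus overstate the fall of seed genes and are not independent support. A difference in development between the genotypes at harvest, or in seed gene expression itself, stays open as untested, and 5 of the 24 markers did not pass in edgeR, all among the 11 others: WRI1 at −0.93, FUS3 at −1.38, PHE1 at −1.87, FIS2 at −1.38 and TT12 at −0.53.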
